A study of Mus musculus with 5 samples.

How the data were processed

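The series profiled chromatin from the uterus of C57BL/6J mice by chromatin immunoprecipitation and sequencing (ChIP-seq). Its 5 samples were single libraries: estrogen receptor α (ERα) after vehicle, ERα after estradiol, RNA polymerase II after vehicle, RNA polymerase II after estradiol, and input chromatin mixed from both treatments. Per the labels' protocols, mice were injected 10 to 14 days after removal of the ovaries with saline vehicle or with 250 ng of estradiol per mouse, and tissue was taken 1 hour later. Only the 2 ERα peak lists were used here. The RNA polymerase II and input libraries were not analysed here.

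Each ERα list was deposited by the authors as 4 columns: chromosome, start, end and a peak name. Per the file headers the coordinates are on the mouse build mm9, which the submitters' processing notes name as well. Those notes also name Partek, with no role or version. The aligner, the peak caller, its settings, and whether the input library served as the control are not given in the sources used here. The lists were deposited per sample and hold no score, height, fold enrichment or read count, so the sequencing depth of each library is unknown and no precision that needs reads can be given. The number inside each peak name runs from 1 to the number of peaks in that list. Its meaning is not stated, and it was used only for the checks that name it. No interval in either list overlapped another interval of the same list. Starts are printed counted from 1, on the reading that the deposited starts follow the BED convention of counting from 0.

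The following was computed from these lists. Peak length was the end minus the start. A vehicle and an estradiol peak were called overlapping when they shared at least 1 bp, counted with bedtools 2.31.1 and again in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with equal counts. Chance overlap was the count after each vehicle peak was placed at random on its own chromosome, between the first and the last peak of both lists together, in 1000 draws. A second form shifted each vehicle peak by 10 to 100 kb in either direction, which keeps the regional density of peaks. Chromosome densities were peaks per Mb of that same span, because chromosome lengths of mm9 were not used here. A cluster was a run of at least 5 peaks with gaps under 12.5 kb. Shares carry 95% Wilson intervals and ratios of peak numbers carry 95% exact binomial (Clopper-Pearson) intervals, computed with scipy 1.17.1. The interval of a median is the exact binomial interval of its order statistics. These intervals cover counting error only and treat peaks as independent, which clustered peaks are not.

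With 1 library per condition there is no replicate check on any difference between vehicle and estradiol, and no p-value is given. The overlap counter was tested on simulated data made from the real peak lengths and spans, and the cluster counter on invented positions with peaks of equal length. The planted sites and clusters were set well apart from other peaks, so these tests check the counting only. All 200 planted shared sites among 2200 simulated sites were recovered, as were all 30 planted clusters, and the mean chance overlap of 18.4 peaks differed little from the 18.5 given by formula.

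The groups, a first set of alternatives, 15 lists of uterine and reference genes, and the rule for the items named in the text were fixed before the data were examined. The rule names the 10 longest estradiol peaks, the 5 longest vehicle peaks and the 5 longest vehicle peaks without an estradiol overlap, by length because the lists hold no score. The reference gene table at hand is on GRCm38, another build than mm9. Coordinates were not moved between builds, so the planned assignment of peaks to genes, the shares of the 15 gene lists (early estrogen response, classical ERα targets, cell cycle and replication, insulin-like growth factor system, Wnt signalling, progesterone and implantation, nuclear receptors and coregulators, myometrium, epithelium, stroma, endothelium, immune cells, housekeeping, liver and neuron), the position of peaks relative to genes, and the motif searches were not carried out. Clusters, 1 Mb windows and the longest estradiol peaks without a vehicle overlap were singled out after their values were seen. The alternatives tried were other definitions of overlap, joining of neighbouring peaks, the longer part of each list, equal list sizes, and other cluster gaps. Some of these were added after seeing the data.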

Results

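ERα binding in the mouse uterus was mapped in 1 library after vehicle and in 1 library after 1 hour of estradiol. ERα is the nuclear receptor through which estradiol acts on the uterus, and mice without ovaries supply little estradiol of their own. The vehicle list held 5184 peaks and the estradiol list 17240 peaks, on the same 20 chromosomes, 1 to 19 and X. The number of reads behind each list is unknown. Each condition rests on a single library, so every difference below is a difference between these 2 libraries with no replicate check.

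The first comparison was of the number and length of the peaks called in each library. The estradiol list was 3.33 times as long as the vehicle list and covered 4630 kb against 1180 kb, a ratio of 3.93. Estradiol peaks were also longer, with a median of 242 bp (quartiles 183 and 317 bp) against 207 bp (quartiles 160 and 270 bp) for vehicle peaks. The mean length was 269 bp ± 132 (SD over 17240 peaks) after estradiol and 228 bp ± 101 (SD over 5184 peaks) after vehicle. The shortest peak was 100 bp in both lists, and 238 estradiol and 150 vehicle peaks had exactly that length.

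The second comparison was whether the sites bound after vehicle were among those bound after estradiol. Of the 5184 vehicle peaks, 3698 overlapped an estradiol peak, or 71.3% (95% Wilson interval 70.1 to 72.5). Random placement of the vehicle peaks gave a mean of 18.2 overlaps and at most 35 in 1000 draws. Shifting each vehicle peak by 10 to 100 kb gave a mean of 56.6 and at most 83. In the other direction, 3663 estradiol peaks overlapped a vehicle peak, or 21.2% (20.6 to 21.9), which left 13577 estradiol peaks (78.8%, 78.1 to 79.4) with no vehicle peak. A group of 1486 vehicle peaks (28.7%, 27.5 to 29.9) had no estradiol peak. The vehicle share fell to 56.4% when the overlap had to cover 50% of both peaks, and to 38.1% when the estradiol list was reduced to its 5184 longest peaks. The estradiol share was 37.2% in that reduced list. With estradiol peaks drawn at random to the vehicle number instead, the vehicle share was 21.5%, a fall that follows from the smaller list by construction.

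Shared sites were the longer ones in both lists. Vehicle peaks with an estradiol overlap had a median length of 230 bp (95% interval of the median 227 to 234), against 166 bp (162 to 169) for those without. Estradiol peaks with a vehicle overlap had a median of 306 bp (300 to 310), against 227 bp (225 to 229) for those without. Among the longest decile of vehicle peaks, 91.9% (89.2 to 94.0) overlapped an estradiol peak, and among the shortest decile 44.6% (40.4 to 48.9) did. Among the longest decile of estradiol peaks, 46.0% (43.7 to 48.4) overlapped a vehicle peak, and among the shortest decile 7.66% (6.49 to 9.01) did. At the 3584 sites where 1 vehicle peak met 1 estradiol peak, the estradiol peak was longer in 2681 (74.8%, 73.4 to 76.2) and the vehicle peak was longer in 890. The median length ratio of estradiol to vehicle at these sites was 1.29 (1.27 to 1.31).

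**Figure D1:**
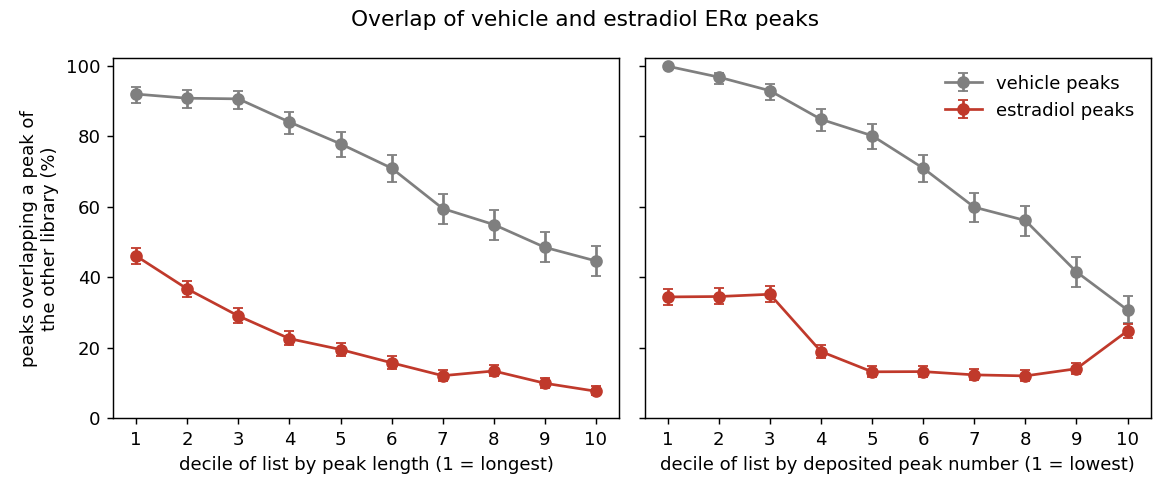
Percent of vehicle peaks (grey) and estradiol peaks (red) that overlap a peak of the other library, by decile of each list, ordered by peak length on the left and by the deposited peak number on the right, with 95% Wilson intervals as bars. By length, the vehicle share falls from 91.9% to 44.6% and the estradiol share from 46.0% to 7.66%.

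Of the 10 longest estradiol peaks, 9 overlapped a vehicle peak, whereas over the whole longest decile 54.0% had none. The longest, 1817 bp on chromosome 17 from 39984036 to 39985852 (mm9, as are all positions given), overlapped the longest vehicle peak, 1760 bp from 39984033 to 39985792. Chromosome 2 held 3 of the 10 longest estradiol peaks. A peak of 1513 bp from 75185725 to 75187237 overlapped 2 vehicle peaks of 492 and 183 bp. Another of 1385 bp from 75194529 to 75195913 overlapped 2 vehicle peaks of 400 and 243 bp, and a peak of 1290 bp from 72884652 to 72885941 overlapped a vehicle peak of 544 bp. On chromosome 11, a peak of 1448 bp from 78894224 to 78895671 overlapped a vehicle peak of only 134 bp. The peak of 1287 bp on chromosome 13 from 52094642 to 52095928 overlapped a vehicle peak of 298 bp. Shorter members of this group lay on chromosome 8 (1201 bp from 129189661 to 129190861, vehicle peak 525 bp), chromosome 1 (1193 bp from 38298098 to 38299290, vehicle peak 780 bp) and chromosome 12 (1150 bp from 16770841 to 16771990, vehicle peak 351 bp). The exception among the 10 was a peak of 1271 bp on chromosome 13 from 112180394 to 112181664, whose nearest vehicle peak lay 6.12 kb away. It was also the longest of the estradiol-only peaks. The next of these were 1136 bp on chromosome 9 from 122086654 to 122087789, 1080 bp on chromosome 6 from 120937521 to 120938600, 1067 bp on chromosome 8 from 122595881 to 122596947 and 1062 bp on chromosome 5 from 114425177 to 114426238. Their nearest vehicle peaks lay 1297, 177, 2.59 and 83.9 kb away in that order.

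Several long peaks were also called in the vehicle library. Whether input chromatin gives signal at these or at the longest estradiol peaks was not checked. After the chromosome 17 peak, the longest vehicle peaks were 899 bp on chromosome 14 from 23576473 to 23577371, which overlapped 2 estradiol peaks of 565 and 243 bp, and 898 bp on chromosome 1 from 169942198 to 169943095, which overlapped none. The next were 897 bp on chromosome 15 from 5377341 to 5378237, with an estradiol peak of 940 bp, and 890 bp on chromosome 17 from 14490549 to 14491438, with an estradiol peak of 1009 bp. Among vehicle peaks without an estradiol overlap, the peak on chromosome 1 was the longest, and its nearest estradiol peak lay 53.1 kb away. The second longest, 785 bp on chromosome 17 from 39983221 to 39984005, ended 0.03 kb before the longest estradiol peak. The third, 610 bp on chromosome 15 from 36009290 to 36009899, lay 0.583 kb from an estradiol peak. The remaining pair, 543 bp on chromosome 14 from 23602338 to 23602880 and 525 bp on chromosome 11 from 3586656 to 3587180, lay 16.3 and 17.6 kb from the nearest estradiol peak.

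Sites seen only after estradiol lay closer to vehicle sites than random positions did. The median distance from the 13577 estradiol-only peaks to the nearest vehicle peak was 61.3 kb, against 313 kb for random placement (300 to 331 kb over 100 placements). Within 10 kb of a vehicle peak lay 18.4% (17.8 to 19.1) of them, against a mean of 3.78% and at most 4.23% after random placement. Random placement does not keep the regional density of peaks, and the local shift was not applied to these distances. The difference therefore cannot separate closeness to single vehicle sites from regions rich in peaks in both lists. Of the 1486 vehicle-only peaks, 529 (35.6%, 33.2 to 38.1) had an estradiol peak within 10 kb. No random placement was made in this direction, and the estradiol list is the longer one, so this share cannot be set against those above.

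Peaks formed more clusters than random placement gave in both libraries. The estradiol list formed 363 clusters of at least 5 peaks with gaps under 12500 bp, which held 2518 peaks (14.6% of the list), and the vehicle list formed 13, which held 75 peaks (1.45%). These counts depend on the gap allowed between peaks: gaps under 5 kb gave 155 estradiol and 2 vehicle clusters (5.30% and 0.193% of peaks), and gaps under 25 kb gave 605 and 38 (27.7% and 4.38%). The longer part of each list gave 121 and 2. Joining peaks closer than 500 bp gave 245 and 9. At the gap first used, random placement gave a mean of 0.95 and at most 4 clusters for estradiol and 0 for vehicle. This placement does not keep the regional density of peaks, and the local shift was not applied to clusters. When estradiol peaks were drawn at random to the vehicle number, they formed a mean of 11.8 clusters (4 to 23 in 1000 draws), a range that includes the 13 vehicle clusters. Of the 363 estradiol clusters, 109 (30.0%) held no vehicle peak, 114 held 1, and 140 held 2 or more. These clusters were defined on the longer list, and the share expected without a vehicle peak was not computed. Of the 13 vehicle clusters, 6 overlapped an estradiol cluster.

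The clusters with the most estradiol peaks differed in how many vehicle peaks they held. The largest spanned 76.3 kb of chromosome 14 from 26276673 to 26352923 and held 25 estradiol peaks and 1 vehicle peak. On chromosome 5, the region from 114020123 to 114086273 held 24 estradiol and 2 vehicle peaks, and the region from 125590616 to 125658014 held 16 estradiol peaks and 0 vehicle peaks. The region of chromosome 1 from 92390010 to 92421457 held 16 estradiol peaks and 1 vehicle peak. By contrast, the region of chromosome 5 from 35959535 to 36030082 held 21 estradiol and 6 vehicle peaks, and that of chromosome 15 from 83458800 to 83525863 held 19 and 6. The largest vehicle cluster, on chromosome 10 from 39334499 to 39366692, held 8 peaks in each library.

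**Figure D2:**
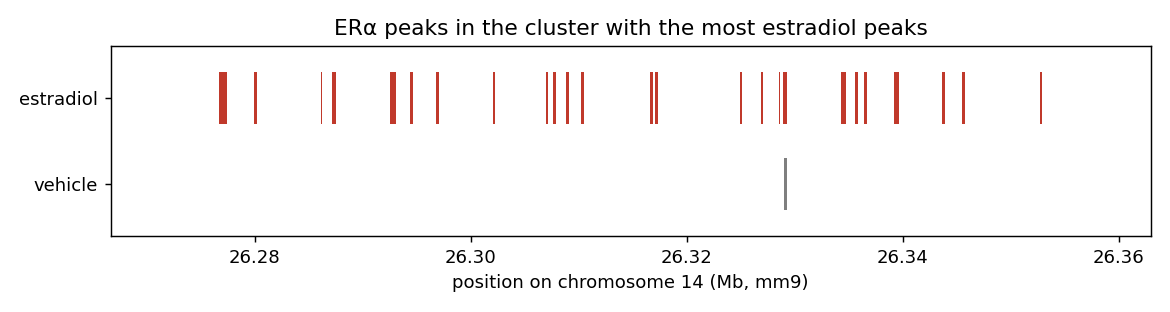
ERα peaks of the estradiol (upper track) and vehicle (lower track) libraries, drawn to scale, over the chromosome 14 cluster with 10 kb on either side; the horizontal axis is the mm9 position in Mb. The cluster holds 25 estradiol peaks and 1 vehicle peak.

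Over windows of 1 Mb, 1765 of the 1981 windows with any peak held more estradiol than vehicle peaks, 147 held equal numbers and 69 held more vehicle peaks. Vehicle peaks made up 23.1% of both lists together, so list length alone would give most windows more estradiol peaks. No expected number of windows was computed. The largest differences in peak number were on chromosome 2 between 167 and 168 Mb (70 estradiol and 7 vehicle peaks) and chromosome 14 between 26 and 27 Mb (76 and 13). Windows on chromosome 8 starting at 124 Mb (62 and 10) and 122 Mb (60 and 10) and on chromosome 5 starting at 114 Mb (59 and 8) followed. They were picked as extremes. Vehicle peaks made up 9.09% (exact binomial interval 3.73 to 17.8) of the chromosome 2 window and 11.9% (5.30 to 22.2) of the chromosome 5 window. The shares were 14.6% (8.01 to 23.7) on chromosome 14 and 13.9% (6.87 to 24.1) and 14.3% (7.07 to 24.7) on chromosome 8. These last intervals hold the 23.1% of both lists together.

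The peaks were spread over all autosomes and were sparse on chromosome X. Chromosome 11 had the highest density in both libraries, with 10.8 estradiol and 2.76 vehicle peaks per Mb of span. Autosomal densities ranged down to 5.29 estradiol peaks per Mb on chromosome 3 and 1.72 vehicle peaks per Mb on chromosome 12. Chromosome X held 185 estradiol peaks (1.07%, 0.93 to 1.24) and 47 vehicle peaks (0.907%, 0.683 to 1.20), although it made up 6.24% of the span. Its density of 1.16 estradiol and 0.295 vehicle peaks per Mb was 6.13 and 7.27 times below the autosomal mean. The ratio of estradiol to vehicle peaks on X was 3.94 (95% exact interval 2.84 to 5.54), an interval that holds the ratio of the whole lists. Among autosomes the ratio ran from 2.76 (2.41 to 3.16) on chromosome 13 to 3.93 (3.44 to 4.49) on chromosome 4, with 3.91 (3.46 to 4.42) on chromosome 11. The intervals of chromosomes 13 and 4 do not meet, but they are too narrow where peaks cluster. These chromosomes were also picked as the extremes among the autosomes, which overstates their difference.

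**Figure D3:**
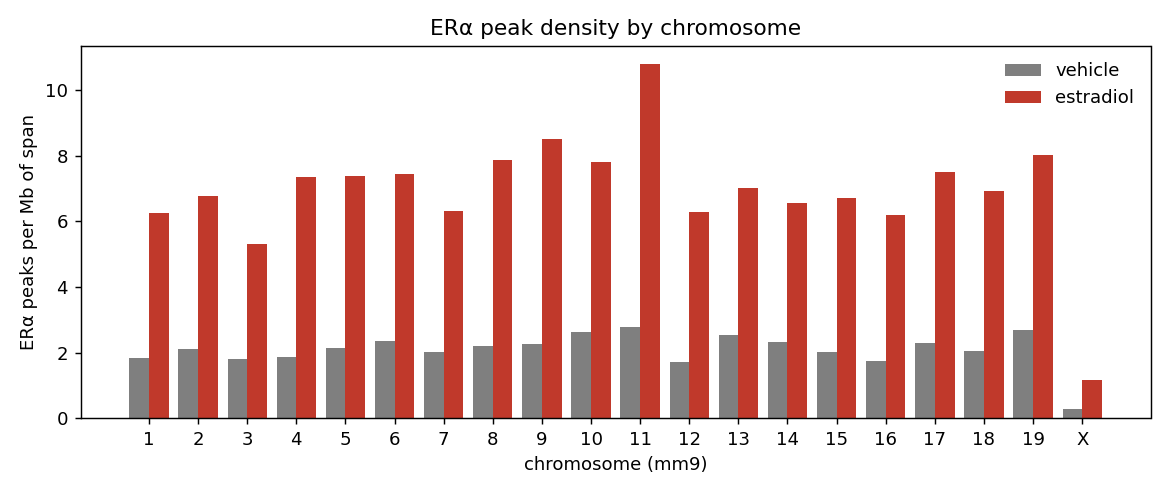
ERα peaks per Mb of the span between the first and last peak of each chromosome, for the vehicle (grey) and estradiol (red) libraries, 1 bar per library and chromosome. Chromosome 11 reaches 10.8 estradiol peaks per Mb and chromosome X 1.16.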

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

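The estradiol list stayed longer than the vehicle list under each alternative that changed both lists alike, with a ratio between 3.21 (peaks closer than 500 bp joined) and 3.33. Keeping the upper part of each list by length leaves 2592 vehicle and 8620 estradiol peaks by construction. The vehicle share with an estradiol overlap was 56.4% with a reciprocal overlap of 50%, 73.4% with gaps of up to 500 bp allowed, 38.1% with the estradiol list reduced to the vehicle number by length, 68.6% in the upper part by peak number, and 21.5% with estradiol peaks drawn at random to the vehicle number. The estradiol share with a vehicle overlap was 16.97%, 23.5%, 37.2% and 20.5% under the first 4 of these settings and 22.4% with neighbouring peaks joined. Random draws to the vehicle number gave an estradiol share of 21.25%, which on average equals that of the full list by construction. The rise to 37.2% goes with keeping the longest peaks, which overlapped vehicle peaks more often in the full list too. The vehicle share falls with a smaller estradiol list by construction, and the choice of peaks also bears on it. Chance overlap rose from 18.2 to 56.6 peaks when peaks were shifted locally. Vehicle clusters numbered 2 with gaps under 5 kb, 38 with gaps under 25 kb and 2 in the longer part of the list. Estradiol clusters numbered 155, 605 and 121 under the same settings, and 11.8 at the vehicle list size. Joining neighbouring peaks gave 9 vehicle and 245 estradiol clusters. The vehicle share on chromosome X was 0.617% in the longer part of the list. Chromosomes 1 to 19 and X were the only ones listed, so that restriction moved nothing. The upper part by peak number, random draws, exclusion of X, the cluster counts and X shares in the longer part, and joined lists for overlaps, clusters and X were chosen after seeing the data. Not run for lack of an mm9 annotation or sequence were the alternatives on gene position, genes with a peak, gene lists, motifs and peaks per gene. With no replicates, none could be left out, and the unknown read depth limits every comparison of list lengths.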

Other observations

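All tests of explanations in this part were chosen after the result was seen, except the count of chromosome X windows. Some regions departed from the ratio of the whole lists. On chromosome 14 between 23 and 24 Mb (mm9) the vehicle library had 24 peaks and the estradiol library 19, so vehicle peaks made up 55.8% (exact binomial interval 39.9 to 70.9) against 23.1% of both lists together. The second longest vehicle peak and the fourth longest vehicle-only peak lay in this window. Chromosome 13 between 23 and 24 Mb had 6 vehicle peaks and 1 estradiol peak. These were the only 2 of 1981 windows with an excess of 5 or more vehicle peaks, and they were picked as extremes. The window richest in vehicle peaks, on chromosome 10 between 96 and 97 Mb, held 27 vehicle and 28 estradiol peaks.

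The estradiol library yielded 3.33 times as many peaks. A candidate explanation is a difference in sequencing depth or ChIP yield acting alike on all sites, in which case the vehicle library would mostly miss weak estradiol sites. With peak length standing in for strength, the share without a vehicle peak rose from 54.0% (51.6 to 56.3) in the longest decile of estradiol peaks to 92.3% (91.0 to 93.5) in the shortest, which goes with that explanation. Ordered by the deposited peak number, the rise was smaller and not steady. That share was 65.6% (63.3 to 67.8) in the first decile, 88.0% (86.4 to 89.4) in decile 8 and 75.2% (73.1 to 77.2) in the last. The lowest 5480 estradiol numbers (31.8% of the list) ran in genome order, as tied entries would. The first decile by number may therefore not hold the strongest sites, and the smaller rise cannot be weighed against the rise by length. The 54.0% is more than such a difference would leave if length ranked the sites exactly, but how far length follows binding strength could not be measured without replicates or reads. A difference in depth or yield therefore stays open, as does the effect of estradiol itself, and with 1 library per condition they cannot be told apart.

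Vehicle peaks without an estradiol peak may be calls near the peak caller's threshold rather than sites lost after estradiol. The share of vehicle peaks overlapped fell from 99.8% (lower bound 98.9) in the first decile of the deposited peak numbers to 30.7% (26.9 to 34.8) in the last decile, which is what that explanation needs. It presumes that high numbers mark weak calls, and the sources used here do not say so. On that reading the explanation may not cover all vehicle-only peaks. In decile 5 of the numbers, 19.9% (16.7 to 23.5) of vehicle peaks had no estradiol peak. The 5 longest vehicle-only peaks had numbers 469, 4787, 542, 622 and 719 of 5184, by falling length. The same site called at a shifted position is argued against, since 7.27% (6.06 to 8.70) of the 1486 peaks had an estradiol peak within 500 bp. Loss of weak sites after estradiol stays open, since it would give the same gradient.

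Chromosome X carried 1.07% of estradiol peaks over 6.24% of the span. Long stretches of chromosome X that reads cannot map to would leave the rest of X at the autosomal density, yet 0% of its 31 windows of 5 Mb (exact interval up to 11.2%) reached the autosomal median of 31 peaks. The highest X window held 26 peaks, the median held 3, and 7 were empty. Weaker coverage of chromosome X stays open. In the vehicle library the X share of the longer part of peaks was 0.516 times that of the shorter part, with an interval from 0.264 to 0.973, as weaker coverage would give, although weaker binding on X would give the same. In the estradiol library the ratio was 0.85, with an interval from 0.629 to 1.15 that holds 1, so that list does not decide it. Both tests were chosen after seeing the data. Poorly mapped sequence scattered along X also stays open without the genome, and no biological explanation was tested, since the design has no group that bears on X.

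The deposited peak numbers hold more structure than a plain index. They fell with length in both lists, with a Spearman correlation across peaks of -0.77 for vehicle and -0.88 for estradiol; peaks are not independent replicates. The lowest numbers form a block in which each chromosome appears once, in ascending position, as tied entries of a sorted list would be laid out. This block held 384 vehicle peaks (7.41% of the list) and 5480 estradiol peaks (31.8%). All 384 vehicle peaks of the block overlapped an estradiol peak, and 34.6% (33.4 to 35.9) of the estradiol block overlapped a vehicle peak. In the estradiol list the overlap did not fall steadily with the number. It was 12.01% (10.6 to 13.6) in decile 8 and 24.8% (22.8 to 26.9) in the last. The longest peak of each list, on chromosome 17, had number 4675 of 5184 in the vehicle list and 6208 of 17240 in the estradiol list.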
